A study of Solanum lycopersicum with 6 samples.

How the data were processed

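Total RNA came from tomato fruit pericarp frozen in liquid nitrogen directly after harvest at 38 days post anthesis, extracted with an SDS-phenol method, and libraries followed standard Illumina protocols, per the labels' protocols. The instrument was an Illumina HiSeq, per the series description. There is 1 file per library, with 3 libraries of wild-type fruit and 3 labelled SlDof1 RNAi. The deposited files give an expected count per gene and an FPKM value (fragments scaled by transcript length and library total), per the file headers. An expected count is the kind of count that is obtained by sharing reads that match several genes or transcripts among them, which leaves fractions. The aligner, the counting program, its settings, the strand of the library and the genome build are not given in the sources used here. Of the expected counts, 94.5% to 94.9% were whole within 0.005. Genes are listed only where a library had reads, so a gene missing from a file was set to 0.

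The plan written before the data were examined assumed FPKM alone and named edgeR on counts as the test to use where the files hold counts, which they do. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (10 counts in a library of median size, 15 in all), which left 16737 genes, and libraries were scaled by TMM factors of 0.967 to 1.04. Groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, group as the only term) and p-values adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are RNAi-labelled over wild type, and a standard error is the absolute log2 fold change divided by the square root of the F statistic. FPKM values are as deposited by the authors, with mean and SD over the 3 libraries of a group. The labels do not say whether replicates are separate plants or fruits, so the p-values measure the spread between these samples only. For floors, which cover counting error only, a count of 0 was treated as allowing 3. The exact and bootstrap intervals given here describe the sampling of genes. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

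Gene lists were tested with camera (preset correlation 0.01) on log2 CPM (prior count 2), adjusted over 14 lists with at least 3 tested members. Estimated correlations and fry, which tests whether a list's genes move one way on balance, were run beside it. Of the lists, 8 passed with the preset correlation, 5 lower and 3 higher. With an estimated correlation 0 passed after adjustment, 4 had an unadjusted p under 0.05, and fry called 11.

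The files pair gene identifiers with no names. The names come from 178 pairs of published gene names and Solyc identifiers in 14 lists, written from memory before the data were examined. The RefSeq table of assembly SLM_r2.1 holds no Solyc identifiers, so each pair was checked only by whether the RefSeq gene of that name or a synonym lies on the chromosome that the identifier gives and, within 2 megabases, between the other pairs of that chromosome. For 115 pairs the place matched. Of these, 23 were matched through a RefSeq gene with another symbol, picked by hand from that table: its synonyms hold the name for 16, and the other 7 (*E8*, *DXS1*, *GGPPS1*, *GGPPS2*, *LCYB*, *GAME9* and *GBSS*) rest on another spelling or on memory. For 59 pairs there was no RefSeq gene of that name, among them *NR*, *CYCB*, *BCAT1*, *GAME25*, *SUS1*, *RBCS2*, the chlorophyll-binding protein genes and the Dof genes, whose names were not checked. The 4 that lay elsewhere (*EBF2*, *GR*, *RBCS4* and *XTH5*) were left out. Another 12 lists, defined by words in product names (such as those for seeds, heat shock and histones), were not made because neither source used here gives product names. Builds differ or are not named, so no coordinates are given. A multiple of 3 was found for 59.4% of the listed lengths.

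Genes named in the text were chosen by a rule set before the data were examined. It takes every Dof family member with a mean FPKM of at least 1 and the remembered candidate; the 8 largest rises and 8 largest falls among called genes with a mean FPKM of at least 5 in the higher group and no overlap of the groups; 16 ripening genes fixed by name; and up to 4 called members of each list with the largest change. *ACO6*, *PMEU1*, *AADC1A*, the clock genes and Solyc08g008500.2 were named after their values were seen. The Dof members other than those that rose appear as counts, or by identifier where a sign changed. Of unnamed genes among the largest changes, 2 that rose and 2 that fell are printed.

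The test was run on simulated counts for the comparison of RNAi-labelled with wild-type fruit (16550 genes, with the dispersions of the real data). It recovered 30% of 50 genes changed 1.5-fold, 88% of 50 changed 2-fold and 100% of 50 changed 4-fold and of 50 changed 8-fold. The changed genes were drawn only from those above a minimum mean count, so recovery at lower counts was not measured. Of 173 calls 14 were false (8.09%), and 0 lists were called where none had been changed. The simulated genes were drawn independently, whereas the estimated correlation within a real list reached 0.823 (photosynthesis). With a term for the 2 libraries that stand apart, described below, that list had 0.23 and the highest was 0.447 (ripening regulators). The 0 therefore does not show how often camera falsely calls a list of correlated genes. Library pairs were compared for duplicates: the lowest chi-square per degree of freedom between 2 libraries of a group was 2.12.

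Alternatives fixed before the data were examined were limma on log2 FPKM with pseudocounts of 0.1 and 0.5, no filter, FPKM of at least 5 in at least 3 libraries, median-of-ratios scaling of counts and of FPKM, quantile normalization, limma without a trend, the replicate number as a block, each library left out, and DESeq2. Limma with a pseudocount of 1, upper-quartile scaling, scaling by total count only, a term for the 2 libraries that stand apart and the fit of the other 4 libraries were added after the data were seen.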

Results

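RNA was sequenced from tomato (*Solanum lycopersicum*) fruit pericarp, the fleshy wall of the fruit, harvested at 38 days post anthesis. The 6 libraries fall into 2 groups: 3 from wild-type fruit and 3 from fruit labelled SlDof1 RNAi. Dof proteins are a plant family of zinc-finger transcription factors, and RNAi is the silencing of a gene by double-stranded RNA. Total expected counts were 9608643, 9836701 and 10002358 in wild-type libraries 1 to 3 and 9881755, 9942009 and 9641678 in RNAi-labelled libraries 1 to 3. The files listed 20944 to 21206 genes per library, 23709 in at least 1 library, and 16737 had enough counts to be tested. The most abundant gene took 2.34% to 2.52% of the counts of a library. Across genes, which are not independent replicates, the log2 CPM (counts scaled to library size) of 2 libraries correlated with r of 0.9789 to 0.9926 within a group and 0.9581 to 0.9739 between groups.

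The labels do not tie SlDof1 to a gene identifier, so the silencing of the target could not be checked by name, and the Dof family was examined as a whole. Of 17 family members tested, 3 rose in RNAi-labelled fruit and 14 did not pass the test (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes); adjusted over the list alone, 3 rose as well. The edgeR test called 0 members lower, 0 at an unadjusted p under 0.05, and DESeq2 and limma also called 0 lower. At an unadjusted p under 0.05, 1 member was lower without a filter, 1 without wild-type library 1, 2 with a term for the pair of libraries described below and 1 in the 4 libraries without that pair. Of the 32 members fixed beforehand 15 were not tested, 2 because no file lists them and 13 for too few counts, so a fall of an untested member cannot be excluded. Nor can a small fall of a tested member, since the test recovered only 30% of simulated 1.5-fold changes. Those changes were placed only in genes above a minimum mean count. The tested members with the fewest counts lay below it, so larger falls could be missed there. Solyc08g008500.2, an untested member named after its values were seen, lay at 1.28 ± 0.758 and 0.377 ± 0.41 FPKM (SD, n = 3; edgeR without a filter, unadjusted p = 0.0351, adjusted p = 0.204). A member remembered as number 1 of the family, Solyc01g096120.2, had rounded counts of 0, 1 and 0 in wild-type libraries 1 to 3 and 15, 15 and 13 in RNAi-labelled libraries 1 to 3 (edgeR adjusted p = 0.00208); whether it is SlDof1 is unverified. The Dof gene Solyc06g075370.2 rose from 15.1 ± 2.33 to 24.8 ± 2.28 FPKM (SD, n = 3; edgeR adjusted p = 0.0137), and Solyc06g076030.2 from 1.46 ± 0.232 to 2.82 ± 0.18 FPKM (edgeR adjusted p = 0.0251). The Dof gene Solyc06g075370.2 did not pass without wild-type library 2 or 3 (adjusted p up to 0.0603), and Solyc06g076030.2 did not pass without wild-type library 1 or 2 or RNAi-labelled library 1 or 2 (adjusted p up to 0.101). With DESeq2, which called 2 family members higher, Dof Solyc06g076030.2 did not pass (adjusted p = 0.0657), nor did it with limma after quantile normalization (adjusted p = 0.0514), and with the replicate number as a block in edgeR neither gene did (adjusted p = 0.0644 for Solyc06g075370.2 and 0.112 for Solyc06g076030.2). Only 1 Dof member passed without wild-type library 2, and 5 passed with a term for the pair of libraries that stands apart, described below. Because the targeted gene could not be checked, the libraries are called RNAi-labelled throughout.

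The comparison of RNAi-labelled with wild-type fruit addresses which genes the 2 genotypes express differently at this stage. RNAi-labelled fruit had lower transcript levels of genes that act in ripening: cell wall enzymes such as the polygalacturonase *PG2a* (7.86-fold lower), the lipoxygenase *LOXC* (5.37-fold lower), the ethylene-synthesis gene *ACS4* (4.06-fold lower) and the carotenoid-synthesis gene *PSY1* (1.87-fold lower). In the other direction, 3 genes for the small subunit of Rubisco, 3 for steroidal glycoalkaloid synthesis and 2 of the cuticle rose. Of 16 ripening genes chosen before the data were examined, 11 fell and 5 did not pass the test, and the fitted log2 fold change of all 16 was below 0. Without RNAi-labelled library 1 only 5 of them fell, and without RNAi-labelled library 2 only 6. Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2065 of 16737 genes (12.3%), of which 1094 rose and 971 fell. A change of at least 2-fold was found for 670 of them, 401 higher and 269 lower. The FPKM of the groups did not overlap for any of the 2065 called genes. Among all tested genes the groups did not overlap for 31%, where chance gives 10% for 3 against 3 (1 of the 10 splits).

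Wild-type library 1 and RNAi-labelled library 3 stood apart from the other 4 libraries. The first principal component of the log2 CPM (51.5% of the variance) separated the groups. The second (30.4%) put these 2 libraries at 32.6 and 32.2 and the other 4 between -18.3 and -13.7. Between the 4 other libraries alone, 3693 genes passed the edgeR test, 1922 higher and 1771 lower, and 2012 of the 2065 genes were among them. With a term for the 2 libraries in the edgeR model 5384 passed, 2664 higher and 2720 lower, but as each group holds 1 of the 2 libraries, the term leaves the fold changes nearly as they were and mainly lowers the residual spread. Of the 16 ripening genes, 15 fell in the 4 libraries and 16 with the term. Both fits use a split that was found in these same data, which lowers the spread by selection. Their counts of calls can therefore be too high. Chi-square per degree of freedom was 2.12 between wild-type libraries 2 and 3 and 2.92 between RNAi-labelled libraries 1 and 2. It was 14.1 to 16.9 for the other pairs within a group. The number of called genes fell to 1108 without wild-type library 2, 1150 without wild-type library 3, 1142 without RNAi-labelled library 1 and 1192 without RNAi-labelled library 2.

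**Figure D1:**
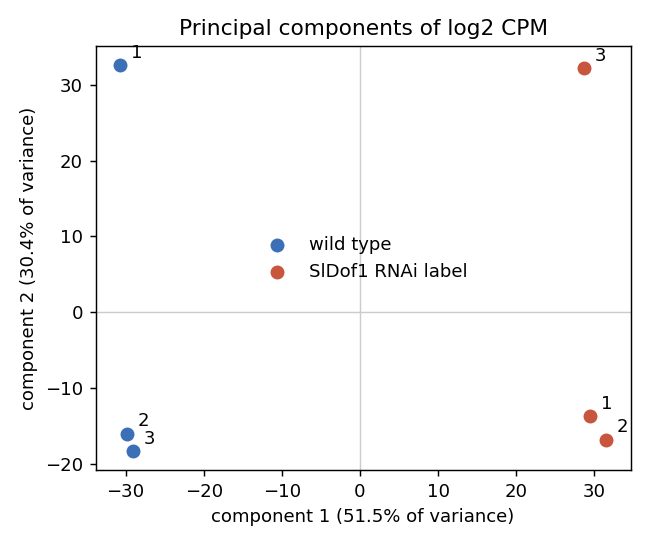
Scores of the 6 libraries on the first 2 principal components of log2 CPM (no unit), with 51.5% and 30.4% of the variance; blue points are wild-type and red points RNAi-labelled libraries, numbered by replicate. Component 1 separates the groups, and component 2 sets wild-type library 1 (32.6) and RNAi-labelled library 3 (32.2) apart from the other 4.

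Among regulators of ripening, transcript levels were lower in RNAi-labelled fruit for *RIN* (Solyc05g012020.2), a MADS-box transcription factor needed for ripening, and *NOR* (Solyc10g006880.2), a NAC transcription factor needed for ripening. *RIN* fell from 407 ± 107 to 243 ± 45.1 FPKM (SD, n = 3; log2 fold change -0.80 ± 0.19 SE, edgeR adjusted p = 0.0288), and *NOR* from 261 ± 27.6 to 193 ± 15 FPKM (log2 fold change -0.49 ± 0.10 SE, edgeR adjusted p = 0.0154). The related MADS-box genes *FUL1* and *FUL2* fell by 0.38 and 0.47 on the log2 scale. In all, 4 of 10 tested regulators fell and 6 did not pass; adjusted over the list alone, 5 fell. Among those that did not pass were *CNR* (log2 fold change -0.25, edgeR adjusted p = 0.356), *TAGL1* (-0.33, adjusted p = 0.0777) and *AP2a* (-0.25, adjusted p = 0.158). The list as a whole was lower by camera with a preset correlation (median log2 fold change -0.291, adjusted p = 0.00323), but not with an estimated one (adjusted p = 0.348 with an estimated correlation). In the 4 libraries left without wild-type library 1 and RNAi-labelled library 3, 6 regulators fell and 1 rose. Without RNAi-labelled library 1 or 2, *RIN*, *NOR* and *FUL2* did not pass edgeR's test (adjusted p up to 0.118, 0.0813 and 0.0892), and of the fits that leave out 1 library *FUL1* passed only in that without wild-type library 1 (adjusted p up to 0.0933). *RIN* did not pass with limma on log2(FPKM + 1), nor did *NOR* and *FUL2* after quantile normalization (limma adjusted p = 0.0656, 0.0644 and 0.0515; the highest over the alternatives that leave out no single library were 0.082, 0.0985 and 0.11). With limma without the trend, with the replicate number as a block in edgeR, and without RNAi-labelled library 1 or 2, 0 regulators fell.

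In ethylene synthesis, the transcripts of *ACS2* and *ACS4*, which encode synthases of the ethylene precursor ACC active during ripening, were lower in RNAi-labelled fruit. *ACS4* (Solyc05g050010.2) fell from 85.2 ± 17 to 21.8 ± 1.56 FPKM (SD, n = 3; log2 fold change -2.02 ± 0.14 SE, edgeR adjusted p = 0.00013), and *ACS2* (Solyc01g095080.2) from 487 ± 85.4 to 288 ± 46.3 FPKM (-0.81 ± 0.15 SE, edgeR adjusted p = 0.00946). Of the ACC oxidase genes, which encode the last step of the pathway, *ACO5* fell from 359 ± 17.8 to 119 ± 6.15 FPKM (edgeR adjusted p = 3.28e-05). *ACO4* rose from 29.6 ± 4.76 to 47.7 ± 4.96 FPKM (edgeR adjusted p = 0.0165). *ACO6*, named after its values were seen, rose from 446 ± 47.4 to 660 ± 47 FPKM (edgeR adjusted p = 0.0143). *ACO1*, the most abundant of the ripening genes chosen beforehand, was at 11500 ± 1440 and 9870 ± 969 FPKM, a difference that did not pass (edgeR adjusted p = 0.206). In all, 3 of 9 tested members fell, 2 rose and 4 did not pass, with the same 5 calls adjusted over the list alone, and the list as a whole was not past the threshold of camera (camera adjusted p = 0.368). By fry the list was lower (fry adjusted p = 0.0435). In the 4 libraries that do not stand apart, 4 fell and 4 rose. Without RNAi-labelled library 1 or 2 the fall of *ACS2* did not pass (edgeR adjusted p up to 0.053), and without wild-type library 2 or 3 or RNAi-labelled library 1 the rise of *ACO4* did not (edgeR adjusted p up to 0.0774). The rise of *ACO6* did not pass without wild-type library 2 or 3 or RNAi-labelled library 2 (edgeR adjusted p up to 0.0689), nor with the replicate number as a block (edgeR adjusted p = 0.0919).

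Of 15 tested genes of ethylene perception and response, 6 fell in RNAi-labelled fruit. The receptor genes *NR* (Solyc09g075440.2) and *ETR6* (Solyc09g089610.2) fell by 0.68 and 1.22 on the log2 scale (edgeR adjusted p = 0.00662 and 0.000419). *EIL2*, of the EIN3-like transcription factors that act downstream of the receptors, fell from 78.9 ± 7.13 to 50.3 ± 4.37 FPKM (SD, n = 3; edgeR adjusted p = 0.00461), and *EBF1*, an F-box gene whose product directs the breakdown of those factors, from 203 ± 18.1 to 138 ± 3.08 FPKM (edgeR adjusted p = 0.00398). The ethylene-responsive gene *E8* (Solyc09g089580.2) fell from 4670 ± 121 to 3480 ± 101 FPKM (edgeR adjusted p = 0.00882), whereas *E4* did not pass at 1910 ± 394 and 1480 ± 412 FPKM (edgeR adjusted p = 0.3). The other 9 did not pass, and adjusted over the list alone 6 fell as well. The list was lower by camera with a preset correlation (median log2 fold change -0.341, adjusted p = 0.00239; adjusted p = 0.161 with an estimated correlation). In the 4 libraries that do not stand apart, 8 fell. *E8* did not pass without RNAi-labelled library 1 (edgeR adjusted p = 0.0656) or with limma after quantile normalization (adjusted p = 0.623). With the replicate number as a block, *NR* (edgeR adjusted p = 0.0521) and *E8* did not pass, and 3 genes of the list fell.

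**Figure D2:**
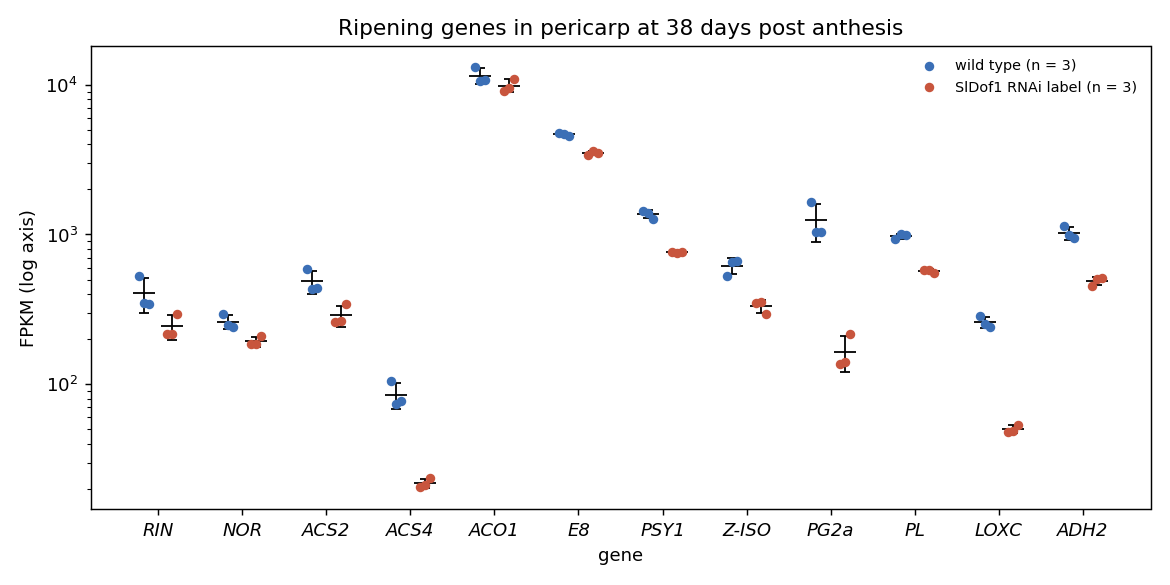
FPKM (log axis) of 12 ripening genes in each library; blue points are the 3 wild-type and red points the 3 RNAi-labelled libraries, and bars give the mean and SD. The red points lie below the blue ones for 11 of the genes shown. For *ACO1* (11500 ± 1440 and 9870 ± 969 FPKM) they overlap. The genes shown are a selection that leaves out *CNR*, *AP2a* and *E4*, ripening genes fixed beforehand whose groups overlap too. The 11 is therefore not a share of the ripening genes fixed beforehand.

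In the synthesis of isoprenoid precursors and carotenoids, the pigments of the ripe fruit, 8 of 22 tested genes fell in RNAi-labelled fruit. *PSY1* (Solyc03g031860.2), the fruit phytoene synthase, fell from 1370 ± 89.4 to 760 ± 2.88 FPKM (SD, n = 3; log2 fold change -0.90 ± 0.08 SE, edgeR adjusted p = 0.000441). *Z-ISO* (Solyc12g098710.1), a carotene isomerase, fell from 618 ± 77.1 to 332 ± 33.1 FPKM (edgeR adjusted p = 0.00201), and *PDS*, phytoene desaturase, from 45.2 ± 4.36 to 28.3 ± 2.18 FPKM (edgeR adjusted p = 0.00267). The lycopene cyclase gene *CYCB* had the largest fall of the list, by 1.46 on the log2 scale (edgeR adjusted p = 0.000788). The other 14 did not pass; adjusted over the list alone, 12 fell and 1 rose. The list was lower by camera with a preset correlation (median log2 fold change -0.308, adjusted p = 3.23e-05; adjusted p = 0.0875 with an estimated correlation). The 4 libraries that do not stand apart gave 13 falls. Without wild-type library 2 or RNAi-labelled library 1 or 2, 5 fell.

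Among cell wall genes, RNAi-labelled fruit had less transcript of several enzymes that act on pectin and hemicellulose. *PG2a* (Solyc10g080210.1), the ripening polygalacturonase, fell from 1240 ± 348 to 165 ± 44.1 FPKM (SD, n = 3; log2 fold change -2.97 ± 0.24 SE, edgeR adjusted p = 0.000204). *MAN4a* (Solyc01g008710.2), an endo-mannanase, fell from 49.5 ± 6.68 to 5.05 ± 0.96 FPKM (-3.35 ± 0.16 SE, edgeR adjusted p = 3.02e-05). *PL* (Solyc03g111690.2), a pectate lyase with a role in softening, fell from 977 ± 37.6 to 573 ± 14.3 FPKM (edgeR adjusted p = 0.000629), and *XYL1* fell at a low level, from 2.58 ± 0.236 to 0.523 ± 0.0577 FPKM (edgeR adjusted p = 0.000291). The 2 members that rose were the cellulase gene *CEL2*, from 0.303 ± 0.218 to 1.77 ± 0.209 FPKM (edgeR adjusted p = 0.00793), and the pectin methylesterase gene *PMEU1*, named after its values were seen, from 112 ± 10.9 to 199 ± 12.8 FPKM (edgeR adjusted p = 0.00259). In all, 7 of 10 tested members fell, 2 rose and 1 did not pass, with the same 9 calls adjusted over the list alone; in the 4 libraries that do not stand apart, 7 fell and 2 rose. The list was lower by camera with a preset correlation (median log2 fold change -0.983, adjusted p = 0.000169; adjusted p = 0.0875 with an estimated correlation).

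Most of the tested genes for the synthesis of aroma volatiles fell in RNAi-labelled fruit. *LOXC* (Solyc01g006540.2), a lipoxygenase needed for fatty-acid-derived volatiles, fell from 260 ± 23.5 to 50.3 ± 2.95 FPKM (SD, n = 3; log2 fold change -2.42 ± 0.10 SE, edgeR adjusted p = 9.51e-06). *ADH2* (Solyc06g059740.2), an alcohol dehydrogenase that acts on volatile aldehydes, fell from 1020 ± 102 to 490 ± 32.7 FPKM (edgeR adjusted p = 0.000378), and the lipoxygenase gene *LOXB* from 945 ± 30.7 to 466 ± 24.8 FPKM (edgeR adjusted p = 0.00017). *AAT1*, an alcohol acyltransferase that makes acetate esters, fell from 1410 ± 353 to 818 ± 181 FPKM (edgeR adjusted p = 0.0269). The member that rose was the aromatic amino acid decarboxylase gene *AADC1A*, named after its values were seen, from 29.2 ± 5.87 to 52.9 ± 9.51 FPKM (edgeR adjusted p = 0.0163). In all, 7 of 9 tested members fell, 1 rose and 1 did not pass, with the same 8 calls adjusted over the list alone. The list was lower by camera with a preset correlation (median log2 fold change -0.774, adjusted p = 3.23e-05; adjusted p = 0.244 with an estimated correlation). The 4 libraries that do not stand apart gave 7 falls and 1 rise, and without RNAi-labelled library 1 or 2, 4 fell. *AAT1* did not pass without wild-type library 3 or RNAi-labelled library 1 or 2 (edgeR adjusted p up to 0.115), nor with limma on log2(FPKM + 1) (adjusted p = 0.0635). *AADC1A* did not pass without wild-type library 2 or 3 (edgeR adjusted p up to 0.075).

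Transcripts of the small subunit of Rubisco, the carbon-fixing enzyme of photosynthesis, were higher in RNAi-labelled fruit. *RBCS2* (Solyc03g034220.2) rose from 333 ± 15.8 to 582 ± 37.7 FPKM (SD, n = 3; log2 fold change 0.75 ± 0.09 SE, edgeR adjusted p = 0.00134). *RBCS1* rose from 8.45 ± 2.47 to 21.1 ± 4.15 FPKM (edgeR adjusted p = 0.0109) and *RBCS3* from 4.8 ± 1.17 to 12.7 ± 2.23 FPKM (edgeR adjusted p = 0.00629). The other 6 of the 9 tested members, chlorophyll-binding protein genes, did not pass, and adjusted over the list alone 3 rose as well. Of the 9, 6 rose in the 4 libraries that do not stand apart. The list was higher by camera with a preset correlation (median log2 fold change 0.718, adjusted p = 0.00585; adjusted p = 0.491 with an estimated correlation), but did not pass without wild-type library 1 (camera adjusted p = 0.0896, median log2 fold change 0.29). It was the only list called by camera that fry did not call (fry adjusted p = 0.119). The genes of both families are near-identical copies between which reads could be split, so single members are uncertain.

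In the list of cutin and outer-epidermis genes, which mark the skin of the fruit, *GPAT6* (Solyc09g014350.2), an acyltransferase of cutin synthesis, rose from 0.353 ± 0.146 to 1.37 ± 0.236 FPKM (SD, n = 3; edgeR adjusted p = 0.00835). *CD2* (Solyc01g091630.2), a homeodomain regulator of the cuticle, rose from 24 ± 2.61 to 35.5 ± 0.761 FPKM (edgeR adjusted p = 0.0131). In all, 2 of 5 tested members rose and 3 did not pass; adjusted over the list alone, 4 rose. The list was higher by camera with a preset correlation (median log2 fold change 0.566, adjusted p = 0.00323; adjusted p = 0.113 with an estimated correlation). In the synthesis of steroidal glycoalkaloids, the bitter defence compounds of green fruit, *GAME12* (Solyc12g006470.1) rose from 4.72 ± 0.481 to 9.85 ± 0.592 FPKM (edgeR adjusted p = 0.00257), *GAME11* from 4.72 ± 0.813 to 8.19 ± 0.488 FPKM (edgeR adjusted p = 0.0184) and *GAME25* from 14.7 ± 2.28 to 24.3 ± 2.64 FPKM (edgeR adjusted p = 0.0198). In that list 3 of 5 tested members rose and 2 did not pass, with 3 also adjusted over the list alone, and the list was higher by camera with a preset correlation (median log2 fold change 0.668, adjusted p = 0.00323; adjusted p = 0.113 with an estimated correlation). The epidermal markers moved in the same direction as the glycoalkaloid and photosynthesis genes. When wild-type library 1 and RNAi-labelled library 3 were left out, 3 cutin genes and 4 glycoalkaloid genes rose. *CD2* and *GAME25* did not pass without wild-type library 3 or RNAi-labelled library 1 or 2 (edgeR adjusted p up to 0.0581 and 0.0791), and *GAME11* did not without these or wild-type library 2 (edgeR adjusted p up to 0.0811). *GPAT6* did not pass after quantile normalization (limma adjusted p = 0.0523).

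**Figure D3:**
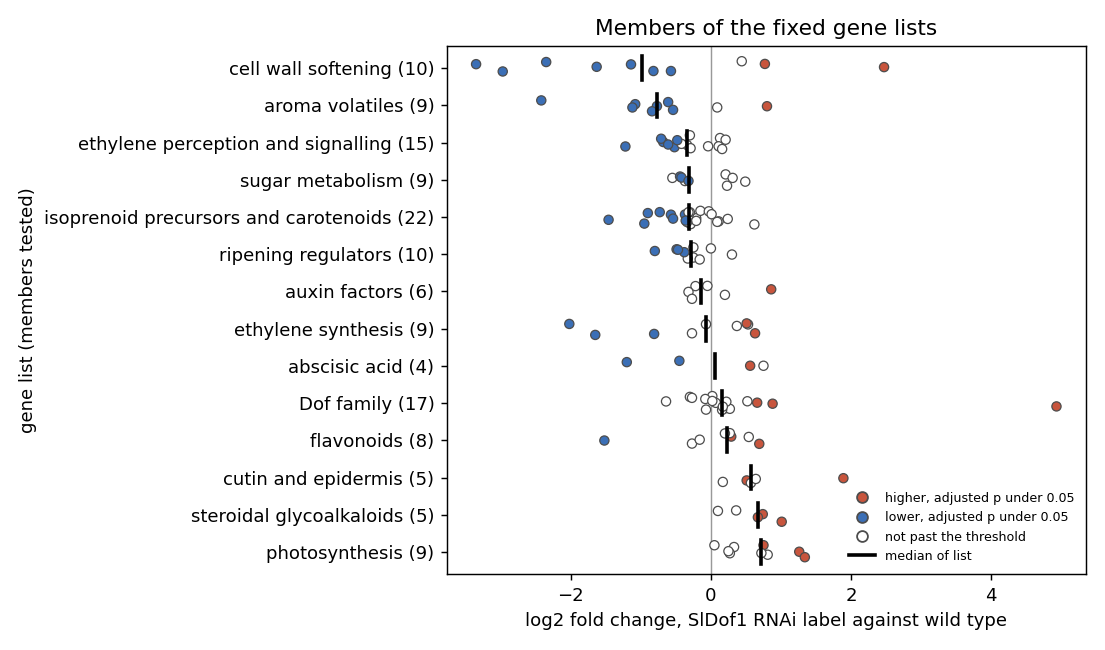
Log2 fold change, RNAi-labelled against wild type (3 libraries each), of each tested member of 14 gene lists, with the number tested in parentheses and a black bar at the median. Red members rose, blue members fell and open circles did not pass the edgeR threshold of 0.05; medians run from -0.983 for cell wall softening to 0.718 for photosynthesis, and the Dof member at the far right has 0, 1 and 0 counts in wild type.

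The other 4 lists were not past the threshold by camera. By fry the abscisic acid and sugar lists were lower (fry adjusted p = 0.0435 and 0.0081). The flavonoid and auxin lists did not pass by fry either (fry adjusted p = 0.67 and 0.51). In the abscisic acid list (adjusted p = 0.416), *NCED1*, the rate-limiting gene of abscisic acid synthesis, fell from 224 ± 6.05 to 170 ± 8.25 FPKM (SD, n = 3; edgeR adjusted p = 0.00695). Of the genes for its breakdown, *CYP707A2* fell from 302 ± 29 to 137 ± 11.7 FPKM (edgeR adjusted p = 0.000235) and *CYP707A1* rose from 37.1 ± 5.25 to 56.9 ± 7.47 FPKM (edgeR adjusted p = 0.0237); 1 of 4 did not pass, and adjusted over the list alone 4 passed. The median log2 fold change of this list was 0.0552 and its mean -0.0843. In the flavonoid list (adjusted p = 0.598), the chalcone synthase gene *CHS2* (Solyc05g053550.2) fell from 49.7 ± 4.77 to 18 ± 1.84 FPKM (edgeR adjusted p = 0.000179). The flavonol regulator *MYB12* rose from 13.1 ± 2.96 to 22 ± 4.11 FPKM (edgeR adjusted p = 0.0476), *PAL5* rose from 57.9 ± 1.07 to 73.7 ± 3.89 FPKM (edgeR adjusted p = 0.041), and 5 of 8 members did not pass, with the same 3 calls adjusted over the list alone. In the sugar list (adjusted p = 0.394), *SUS1*, *SUS3* and *SPS*, which encode enzymes of sucrose metabolism, fell by 0.44, 0.42 and 0.32 on the log2 scale and 6 of 9 did not pass, with 3 also adjusted over the list alone. In the auxin list (adjusted p = 0.962), *IAA27*, an Aux/IAA gene, rose from 12 ± 1.47 to 22.8 ± 1.16 FPKM (edgeR adjusted p = 0.00325) and 5 of 6 did not pass, with 1 adjusted over the list alone; its median was -0.137 and its mean 0.0315. The Dof list also did not pass by camera (camera adjusted p = 0.088), except, as higher, without wild-type library 3 (camera adjusted p = 0.0441). By fry the Dof list was higher (fry adjusted p = 0.032). In leave-one-out fits *PAL5* passed in none (edgeR adjusted p at least 0.0823), and *MYB12* and *SPS* passed only without wild-type library 1 (up to 0.168 and 0.13); with limma on log2(FPKM + 1) *MYB12* and *SPS* did not pass either. *CYP707A1* and *SUS1* did not pass without wild-type library 2 or 3 or RNAi-labelled library 2 (up to 0.105 and 0.0667), nor did *SUS3* without these or RNAi-labelled library 1 (up to 0.0564). With the replicate number as a block, *NCED1* (edgeR adjusted p = 0.085), *CYP707A1*, *MYB12*, *PAL5*, *SUS1*, *SUS3* and *SPS* did not pass.

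Among called genes with a mean of at least 5 FPKM in the higher group and no overlap of the groups, most of the largest changes lay in genes without a name in the fixed lists. Solyc12g038430.1 had 0 counts in each wild-type library and 60, 62 and 95 in RNAi-labelled libraries 1 to 3, at least 24.1-fold higher against a floor of 3 counts per library (edgeR adjusted p = 0.000608). Solyc01g081250.2 had 1, 0 and 0 counts in wild type and 152, 167 and 211 in RNAi-labelled fruit. In the other direction, Solyc10g005120.1 had 115, 125 and 114 counts in wild type and 0, 0 and 1 in RNAi-labelled fruit (edgeR adjusted p = 2.77e-05), and Solyc04g055170.2 fell from 142 ± 13.2 to 8.58 ± 0.66 FPKM (SD, n = 3; 17.2-fold lower, edgeR adjusted p = 5.41e-06). *MAN4a* and *PG2a* were the only genes with a name in the fixed lists among the 8 largest falls under these limits, and there were none among the 8 largest rises. Genes below the FPKM limit, among them the Dof gene Solyc01g096120.2, were not ranked.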

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

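The limma fit with a pseudocount of 1, upper-quartile scaling, total-count scaling, the term for the 2 libraries that stand apart and the fit of the other 4 libraries were chosen after seeing the data. No gene called by edgeR changed sign in any alternative that tested it. For the named genes, 1566 values kept direction and side of the threshold, 137 no longer passed, 12 newly passed and 15 changed sign. DESeq2 called 1973 genes and edgeR without a filter 1941. Lists were not run with DESeq2. The balance of directions went with scaling: 53% of the 2065 called genes were higher, 54.8% for limma on FPKM with median-of-ratios scaling and 53.8% with quantile normalization, against 62.7% of 2052 with total count only and 63.1% to 64.3% for limma on FPKM as deposited. An FPKM of at least 5 left 392 genes changed 2-fold and 1 Dof gene, as fewer genes were tested.

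The replicate numbers do not pair the samples: deviations of same-numbered libraries from their group means correlated at -0.493, 0.279 and -0.521, and no library correlated best with its own number. With the replicate block 877 genes passed, 496 higher and 381 lower, and 1 Dof gene. The term for the 2 libraries gave 5384 genes, 2664 higher and 2720 lower, and 5 Dof genes. The 4 other libraries gave 3693 genes, 1922 higher and 1771 lower. The cause was not tested. Leaving out 1 library gave 1108 to 2038 genes, 583 to 1126 higher, 481 to 912 lower, 549 to 715 changed 2-fold, 7 to 9 lists (the Dof list gained, without wild-type library 3) and 1 to 3 Dof genes. Of the 16 ripening genes 11 fell, against 7 with quantile normalization, 7 without the trend, 5 with the replicate block and 5 to 11 leaving out 1 library (5 without RNAi-labelled library 1, 6 without RNAi-labelled library 2). The fits without wild-type library 2 (1108), wild-type library 3 (1150), RNAi-labelled library 1 (1142) or RNAi-labelled library 2 (1192) had fewer samples, and in each a group kept 1 library that stands apart and 1 that does not.

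With an estimated correlation 0 lists passed (2 among genes with FPKM of at least 5). The auxin list, far from the threshold, changed direction with pseudocounts of 0.1, 0.5 and 1 (camera adjusted p = 0.989, 0.986 and 0.985). It also did without the trend (0.985), without a filter (0.991) and with the replicate block (0.988). Upper-quartile scaling (0.981), total count only (0.951), the term for the 2 libraries (0.654) and the 4 libraries (0.588) gave the same change. Of the fits that leave out 1 library, those without wild-type library 1 (0.632) and RNAi-labelled library 1 (0.833) or 2 (0.95) changed its direction. In the other such fits the auxin list kept its direction (camera adjusted p = 0.712 to 0.749). The cause was not tested. Log2 fold changes near 0 changed sign for Dof Solyc09g010680.2 (-0.01 with a pseudocount of 0.1, -0.03 with median-of-ratios scaling of FPKM, -0.07 with quantile normalization, -0.03 with the replicate block, -0.16 to 0.3 leaving out 1 library), Dof Solyc02g077950.1 (-0.07 with quantile normalization, -0.28 in the 4 libraries, -0.17 to 0.35 leaving out 1), Dof Solyc08g082910.1 (-0.39 to 0.13) and Dof Solyc03g121400.1 (-0.21 to 0.05). The cause was not tested.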

Other observations

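Of the tests below, the one of ripening stage on the 2 libraries that stand apart and both on the fall of the ripening lists were chosen after the results were seen. The bounds of the test of the 2 libraries on those lists were set when its values were already known; it replaced a test with a term for the 2 libraries, which was dropped because the term is balanced over the groups. The bootstrap interval of the clock test was added after its result. The clock genes were written down from memory after the split of the libraries was seen and before their values were. The thresholds that define genes detected in 1 group only were set after the largest changes were seen. The test of their neighbours was added after that of neighbouring pairs and before its own result. The identifiers of the clock genes were not checked against a reference, and those named here were chosen after their values were seen.

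Of 12 clock genes tested, 11 did not pass in the comparison of RNAi-labelled with wild-type fruit. *FKF1*, which encodes a blue-light receptor, fell from 71.58, 79.49 and 81.74 FPKM to 64.21, 60.95 and 63.73 FPKM (edgeR adjusted p = 0.0298), but did not pass in 5 of the 6 fits that leave out 1 library (edgeR adjusted p up to 0.122). *PRR9*, another clock gene, lay at 29.39 FPKM in wild-type library 1 and 31.98 in RNAi-labelled library 3, against 22 and 22.72 in the other wild-type and 21.28 and 22.28 in the other RNAi-labelled libraries, a log2 difference of 0.45 that was larger than that of 88.9% of genes of like expression.

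Wild-type library 1 and RNAi-labelled library 3 differed from the other 4 libraries in 5156 genes by edgeR, 2295 higher and 2861 lower. That split was found in these same data, so the count can be too high. A harvest at another time of day is argued against as the whole cause by the 12 clock genes, *PRR9* included: their median absolute log2 difference was 0.12, at percentile 14.98 of 10000 random lists matched on expression, and the upper end of its bootstrap interval, 0.17, was at percentile 43.6. The median can miss a shift that moves only a few clock genes, so time of day as a part of the cause stays open. After all libraries were thinned to 9608644 counts, the second component kept 30.3% of the variance and the same 2 libraries. The totals were close beforehand: 9608643 and 9641678 in these 2, the lowest, and 9836701 to 10002358 in the other 4. Thinning could thus change little, and it argues only against the totals themselves as the cause. Ripening stage stays open as a candidate explanation: of 35 genes of the ripening lists that fell in RNAi-labelled fruit, ethylene synthesis included, 29 (82.9%) were higher in the 2 libraries, by a median of 0.14 on the log2 scale, against 51.8% of all tested genes and a 95th percentile of 57.1% in random lists. The random genes were drawn singly, so this percentile can be too low for lists of correlated genes. Genes that did not pass were left out, among them *E4*, which was lower in the 2 libraries (1460.43 and 1020.64 FPKM, against 1608.68 to 2152.61 in the other 4). The labels name no batch, and a difference in handling was not tested.

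The genes with at most 3 counts in every library of a group and at least 30 in every library of the other numbered 8, of which 7 were detected in RNAi-labelled fruit and 1 in wild type. That each lies in a block of changed genes is argued against, since 11 of 82 tested neighbours within 10 gene models were called (13.4%, exact 95% interval 6.89 to 22.7), against 12.3% of all tested genes. The number of neighbouring pairs among the 8 genes was 0, which was the bound set beforehand for lines that do not differ at blocks of the genome. That bound was wrong, as decided after the result, because the 95th percentile of random draws was 0 too, so this measure leaves it open. Reads shared with near-identical genes stay open: 3 of the 8 (37.5%) had counts that were not whole in every library of the expressing group. Among tested genes 3.59% had such counts in every library of both groups, a stricter demand, so the shares are not a like comparison. A difference in sequence between the lines was not tested.

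By camera with a preset correlation the lists of regulators, ethylene perception, carotenoids, cell wall and aroma were lower and the photosynthesis list higher in RNAi-labelled fruit, though not with an estimated correlation (adjusted p = 0.0875 to 0.491), and the ethylene synthesis list did not pass with either. Without the 2 libraries that stand apart all 6 lists passed camera in the same direction with the preset correlation (adjusted p up to 0.00181). With an estimated one 0 did there either (camera adjusted p = 0.253 to 0.417). The calls with the preset correlation thus did not rest on these 2 libraries. As each group holds 1 of the 2, a shift that they share would cancel between the groups, so the fit cannot decide on them as a cause. RNAi-labelled fruit that were less advanced in ripening at harvest remain a candidate explanation: 16 of the 16 ripening genes had a log2 fold change below 0. Direct control of these genes by SlDof1 would give the same, so the 2 cannot be told apart with 1 time point. The silencing named by the labels stays untested, since the targeted gene is not identified.

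The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with the most called genes (2065, highest other 0), the most genes changed 2-fold (670, highest other 0) and the most lists (8, highest other 6). In every other split each side mixes wild-type and RNAi-labelled libraries. The difference between the genotypes then adds to the spread within a side and holds calls down. The 0 therefore does not measure how many genes would be called by chance.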
